A study of Mus musculus with 158 samples.

How the data were processed

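The study seeded single fluorescent Sca1+ cKit+ mouse progenitors among bone marrow filler cells, split each clone at day 2.5, sorted part of it for RNA and grew the rest in a pair of sister wells until day 8. The sample labels name the CEL-Seq protocol, and the series text names CEL-Seq2. The deposited table holds counts as whole numbers for 27179 NCBI gene IDs in 158 libraries, without normalization. Per the labels, the authors used featureCounts 1.5.0 and genome build mm10. The aligner, the annotation, the strand and any collapsing of molecular identifiers are not given. IDs were matched to symbols and GRCm38 (mm10) coordinates through the reference gene table, and 25275 matched. The 1904 others, which hold 6.93% of counts, kept their ID.

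Library pool was read from the title of each sample. Sister-well outputs, filler shares and sorted cells came from the labels. Classes, comparisons, filters, gene lists and the rule for named genes were fixed before the data were examined. A clone was classed by which of pDC, cDC1 and cDC2 had output above 0 in both sister wells. Either cDC1 or cDC2 by that rule counted as making cDCs. The pairs of sister wells were averaged, and output entered as log2(mean + 1). Clone libraries with at least 1000 detected genes were used, 142 of 147. Genes with a count in at least 20% of them were tested, 9512 in all. Wells with 0 sorted cells and the unclassed library entered no gene test.

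Gene tests used edgeR 4.0.16 in R 4.3.3, with TMM scaling and a quasi-likelihood F test. Pool and log2 of sorted cells were covariates, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Slopes are log2 changes per doubling of output + 1. The class fit held 4 classes, DC-producing being the mean of 3 of them. Each of the 3 was also compared with no-DC clones, a step added after the mean had been seen. SE was derived from the effect and its F value. The older form of edgeR's fit was chosen after the numbers of genes called in permuted data had been seen, and the newer form is reported as an alternative. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM (prior count 3), adjusted over 126 list tests, then with an estimated correlation and with fry. Correlations used permutation tests with 100000 resamples in scipy 1.17.1 for outputs.

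The named-gene rule took, for each gene comparison, the 10 genes of lowest p in each direction among those that passed, leaving out unnamed, ribosomal protein and mitochondrially encoded genes, plus passing members of the 21 lists. Where fewer than 5 passed it took the 5 of lowest p in each direction. Values of Irf8, Tcf4, Id2, Batf3, Zeb2, Flt3, Csf1r, Siglech, Bcor, Mpo, Cd34 and Kit were always taken. The text names a part of these genes, picked after their values were seen.

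The fits were tested on simulated data of the same design with 200 changed genes. Of genes with a slope of 0.25, 57% (pDC), 40% (cDC1) and 51% (cDC2) were found, and of those with 0.5, 99%, 96% and 99%. For DC-producing clones 22% were found at 1.5 and 91% at 3, and for pDC-only against cDC-only clones 18% at 2 and 70% at 4. Unchanged genes made up 12.9% to 19.2% of calls, above the nominal 5%, so some genes counted as passing are false calls. The simulated counts held no effect of pool or sorted cells. Their spread followed mean expression, with none particular to a gene. The shares found and the shares of false calls may thus differ in the real data. Alternatives covered the scaling, the gene and library filters, DESeq2 1.42.0 and limma-voom, the covariates, the output scale, single sister wells, the class rule, single pools and each pool left out. Reads of multigene families (H2, Ly6, tubulin, histone and ribosomal protein genes, and Gapdh with its pseudogenes) cannot be assigned with certainty.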

Results

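Single mouse hematopoietic stem and progenitor cells carrying a green fluorescent reporter were each grown among unlabelled bone marrow cells, called filler cells, with FLT3 ligand, a cytokine that drives dendritic cell (DC) development. After 2.5 days the fluorescent offspring of each founder, here called a clone, was divided. Part of the clone was sorted for CEL-Seq, an RNA sequencing method that barcodes each well and reads the 3' ends of transcripts. The rest went into a pair of sister wells, whose DCs were measured on day 8. These were plasmacytoid DCs (pDCs), a main source of type I interferon, and the conventional subsets cDC1 and cDC2, which present antigen to T cells. The design asks which transcripts of a clone at day 2.5 went with the DC types its sister wells made later. The labels give neither the unit of DC output nor the number of mice, so each p-value measures spread between clones.

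The series holds 158 libraries in 4 library pools, S1 (40 libraries), D9JS27 (39), JS91 (40) and JS96 (39). A DC type was counted as made when its output was above 0 in both sister wells, with cDC1 and cDC2 judged separately. Clones that made either cDC1 or cDC2 by this rule were counted as making cDCs. By that rule 62 clones made cDCs and pDCs, 31 made cDCs only, 14 made pDCs only and 40, called no-DC clones here, made neither. Only 28 clones had an output of 0 for every lineage in both sister wells. The other no-DC clones had some output in at least 1 sister well. The highest was in a clone of JS91, with 227 for pDCs and 108 for cDC2 in a sister well. Some had cDC1 output in 1 sister well and cDC2 output in the other, and so cDC output in both. These values were 2.86 and 9.9 in a clone of D9JS27, and 6.32 and 6.56 in a clone of JS91. A further 10 libraries came from wells that received 0 sorted cells, and 1 library could not be classed because every output and filler share in its label was 0. The 147 classed clone libraries held 1 to 11 sorted cells. Total counts had a median of 199530, and detected genes a median of 5937. After 5 libraries with fewer than 1000 detected genes were left out, 142 entered the gene tests, with 7651 to 6694662 counts each. Median totals of these were 112536 in S1, 1321858 in D9JS27, 91302 in JS91 and 268895 in JS96. Intervals and floors given below cover counting error only.

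Wells with 0 sorted cells gave small libraries in pools JS91 and JS96. In JS91 the 6 such wells averaged 3.22 ± 0.667 (SD) in log10 total count, against 4.96 ± 0.555 in 33 clone libraries (exact permutation test, two-sided, p = 1.2e-06). In JS96 the 2 such wells averaged 3.11 ± 0.165 against 5.2 ± 0.52 in 37 clone libraries (exact permutation test, two-sided, p = 0.00135). Pools S1 and D9JS27 held 1 such well each, too few for a test, with log10 differences from the clone mean of 0.472 and -0.0106. Over all pools the clone libraries lay 1.67 log10 units higher (146 libraries with a count against 10 wells, two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). Detected genes numbered 5633 ± 2697 (SD, n = 147) in clone libraries and 1238 ± 1825 (SD, n = 10) in those wells (permutation p = 1e-05; exact p = 2.42e-04 in JS91 and 0.00135 in JS96).

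Clones that made DCs gave richer libraries, which bears on the comparison with no-DC clones. Within pools, DC-producing clones detected 2341 more genes than no-DC clones (104 against 38 libraries, two-sided permutation p = 1e-05), and their log10 total count was 0.43 higher (permutation p = 2e-05). The difference in detected genes was 2032 in S1, 2985 in D9JS27 and 4543 in JS96, but -485 in JS91. Between pDC-only and cDC-only clones no difference was detectable (14 against 30 libraries, permutation p = 0.573 for detected genes and 0.612 for total count).

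**Figure D1:**
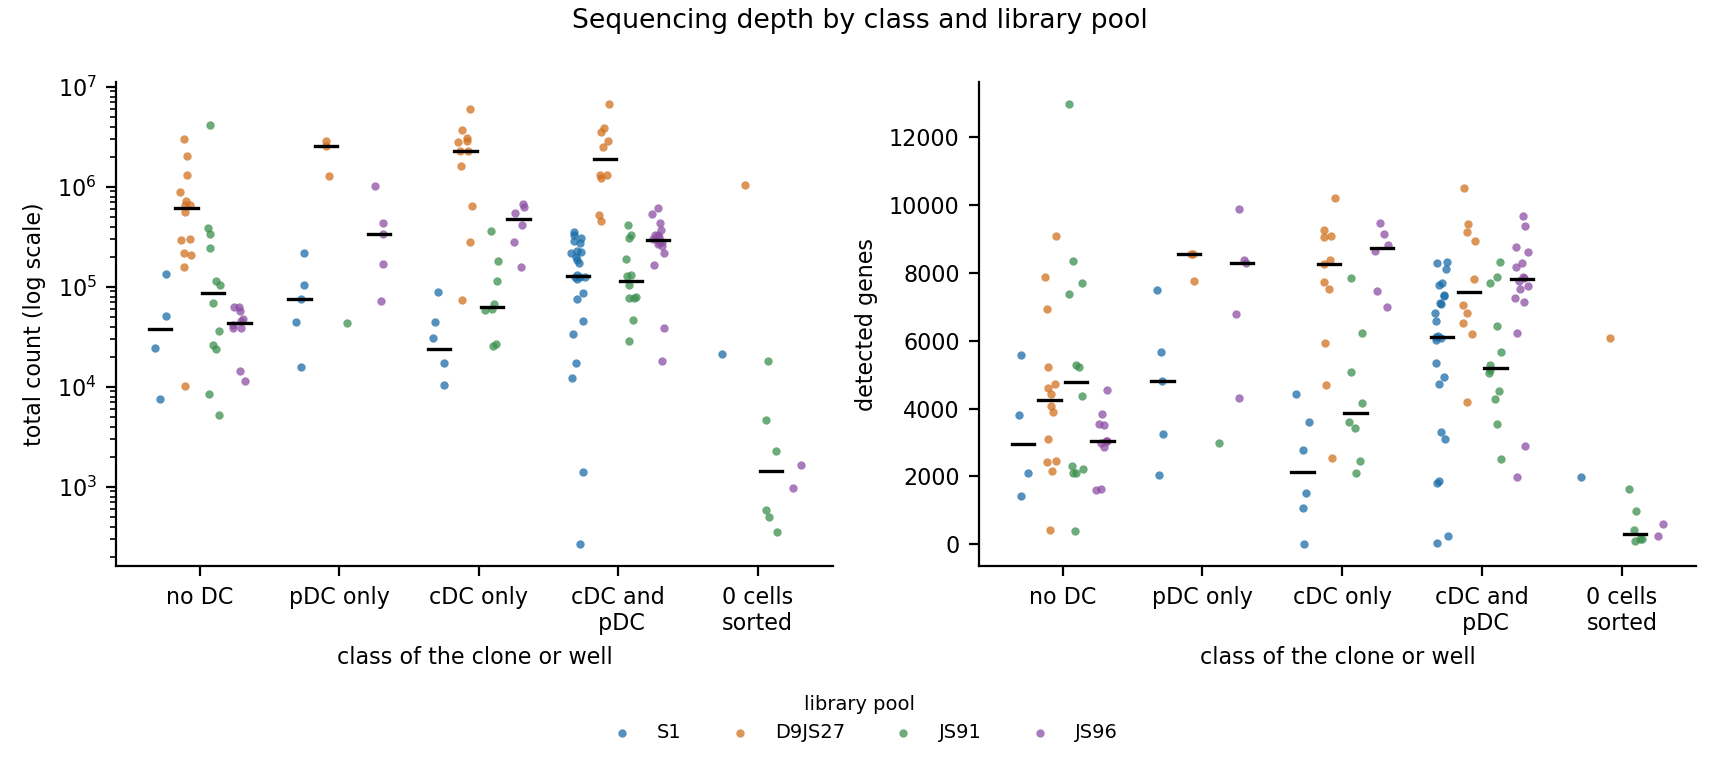
Total count (left, log scale, libraries with 0 counts not drawn) and detected genes (right) of each library by class of the clone or well; points are libraries coloured by pool, and black bars are medians of the libraries of a class and pool where there are at least 3. The well of pool D9JS27 with 0 sorted cells sits at 1037727 counts and 6093 detected genes, within the range of the clone libraries of its pool.

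Sister wells of one clone made similar amounts of each DC type. The Pearson correlation of log2(output + 1) between them was 0.912 for pDCs, 0.86 for cDC1 and 0.886 for cDC2 (n = 147 clones, permutation p = 1e-05 each, the smallest possible). Spearman's rho was 0.914, 0.854 and 0.876 (permutation p = 1e-05 each). Without the 2 clones farthest from the median r was 0.91, 0.854 and 0.879. Within pools r ran from 0.855 to 0.938 for pDCs, from 0.829 to 0.907 for cDC1 and from 0.87 to 0.908 for cDC2. Among clones with output in both wells r was 0.77 for pDCs (n = 76), 0.692 for cDC1 (n = 73) and 0.825 for cDC2 (n = 82).

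The outputs of different DC types were related across clones as well. Pearson's r was 0.836 between cDC1 and cDC2 (rho 0.819), 0.582 between pDC and cDC1 (rho 0.587) and 0.535 between pDC and cDC2 (rho 0.535), each over 147 clones with permutation p = 1e-05 for both. Without the 2 clones farthest from the median r was 0.827, 0.56 and 0.514. Within pools the ranges were 0.754 to 0.942, 0.334 to 0.812 and 0.348 to 0.803. The number of sorted cells was weakly related to DC output (r = 0.243, permutation p = 0.00287; rho = 0.26, p = 0.00149; r without 2 clones 0.24). Within pools that r was 0.378 in S1, 0.316 in D9JS27, 0.175 in JS91 and 0.0156 in JS96, and it passed in S1 alone. By rho, S1 (0.401, unadjusted permutation p = 0.0116) and D9JS27 (0.369, p = 0.0231) passed. The number of sorted cells was related to log10 total count with r = 0.368 (permutation p = 3e-05; rho = 0.285, p = 4.90e-04; r without 2 clones 0.319), and within JS96 with r = -0.108. The family held 9 relations, and the highest Benjamini-Hochberg adjusted p among them was 0.00287.

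**Figure D2:**
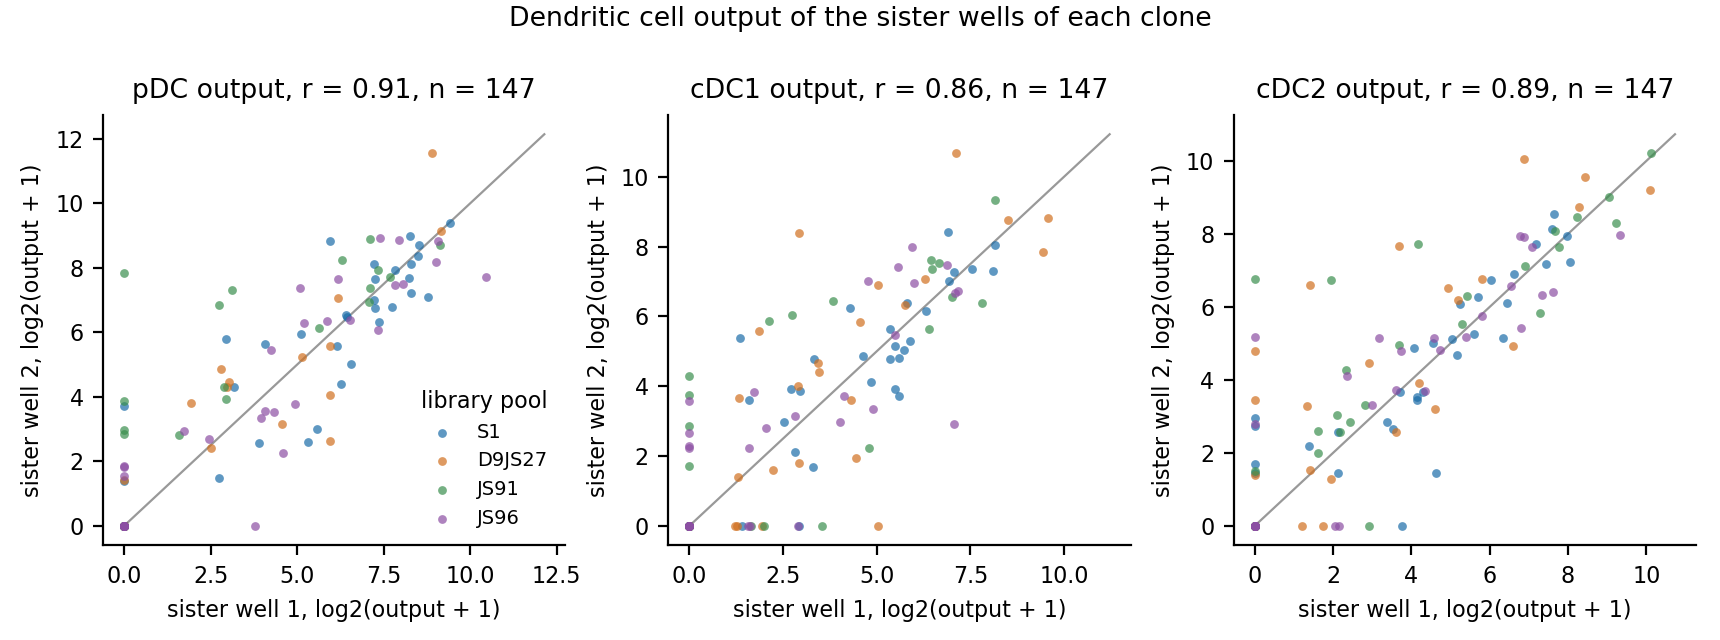
DC output of sister well 2 against sister well 1 of each clone, as log2(output + 1), for pDCs, cDC1 and cDC2; each point is a clone (n = 147), coloured by library pool, and the grey line marks equal output. Points follow the line, with r of 0.912, 0.86 and 0.886.

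Clones that went on to make more pDCs carried fewer transcripts of antigen presentation and monocyte genes at day 2.5. H2-Aa, which encodes an MHC class II alpha chain (Entrez Gene 14960, chromosome 17, 34282744 to 34287823, GRCm38), fell by 1.03 on the log2 scale per doubling of pDC output (SE 0.116, adjusted p = 7.47e-12, n = 142 clones). Many libraries held no count of it. These were 25 of 38 no-DC, 8 of 14 pDC-only and 14 of 30 cDC-only libraries, and 45 of 60 from clones that made both. Of 8 tested MHC class II genes 6 fell and 0 rose (6 fell adjusted over the list alone), among them H2-Eb1 (log2 change -0.80, SE 0.127) and the invariant chain gene Cd74 (-0.72, SE 0.106). Of 13 monocyte and macrophage genes 10 fell and 0 rose (12 fell adjusted over the list alone), among them the coagulation factor gene F13a1 (-0.75, SE 0.112), the lysozyme gene Lyz2 (-0.53, SE 0.0883), the NADPH oxidase gene Cybb (-0.58, SE 0.0895) and the M-CSF receptor gene Csf1r (-0.39, SE 0.0882). The MHC class II list fell as a set (camera adjusted p = 1.76e-11, and adjusted p = 0.00136 with an estimated correlation), as did the monocyte list (camera adjusted p = 3.38e-22, and adjusted p = 3.77e-04 with an estimated correlation). Lgals3, a galectin gene (-0.94, SE 0.109), and Cd7, a surface receptor gene (-0.88, SE 0.129), fell too.

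Genes that mark pDCs fell with pDC output as well. Of 16 tested members of the pDC list 7 fell and 0 rose (9 fell adjusted over the list alone; camera adjusted p = 2.88e-11, and adjusted p = 0.00719 with an estimated correlation). They included the lectin gene Siglech (log2 change -0.67, SE 0.122), Ly6d (-0.73, SE 0.131), which the lymphoid list shares, the transcription factor gene Spib (-0.54, SE 0.125) and the interferon regulator gene Irf7 (-0.35, SE 0.103). Tcf4, the transcription factor gene that specifies pDCs, had a value of -0.01, SE 0.0428 (adjusted p = 0.943). Of 16 pan-DC and DC progenitor genes 8 fell (10 adjusted over the list alone; camera adjusted p = 7e-15, and adjusted p = 7.04e-04 with an estimated correlation), among them the cathepsin gene Ctss (-0.40, SE 0.0615). Of 13 cDC2 genes 5 fell (7 adjusted over the list alone; camera adjusted p = 4.78e-06, and adjusted p = 0.0476 with an estimated correlation). Of 12 interferon response genes 2 fell (4 adjusted over the list alone; camera adjusted p = 4.99e-07, and adjusted p = 0.00599 with an estimated correlation), and of 19 cytokine receptor genes 3 fell (5 adjusted over the list alone; camera adjusted p = 9.77e-07, and adjusted p = 0.0101 with an estimated correlation). By fry, which tests a list against no change, the pDC (adjusted p = 0.179), cDC2 (0.789), interferon response (0.387) and cytokine receptor lists (0.984) did not pass. Between pDC-only and no-DC clones the pDC list did not pass by camera either (adjusted p = 0.3045), with 1 member lower and 0 higher. Siglech had a value of 0.48, SE 1.08 (adjusted p = 0.926) there.

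Replication and growth genes rose with pDC output by small amounts. Of 30 DNA replication genes 8 rose and 0 fell (22 rose adjusted over the list alone; camera adjusted p = 4.26e-12, but adjusted p = 0.075 with an estimated correlation), including the dUTPase gene Dut (log2 change 0.23, SE 0.0464) and the replication helicase gene Gins2 (0.30, SE 0.0676). Of 20 glycolysis and MYC genes 6 rose (15 adjusted over the list alone; camera adjusted p = 7.86e-07, but adjusted p = 0.0985 with an estimated correlation), including Myc (0.25, SE 0.0589) and the nucleolar protein genes Ncl (0.16, SE 0.032) and Npm1 (0.14, SE 0.0294). Of 83 ribosomal protein genes 23 rose (47 adjusted over the list alone; camera adjusted p = 5.14e-09, but adjusted p = 0.312 with an estimated correlation). With library totals alone as scaling the ribosomal protein list did not pass (camera adjusted p = 0.1507), while the replication and the glycolysis and MYC lists did. The stem and progenitor genes Cd27 (0.28, SE 0.0694), Angpt1 (0.26, SE 0.0798) and Mllt3 (0.26, SE 0.0794) rose and Ly6a, which encodes Sca1, fell (-0.38, SE 0.125). Their list of 13 genes did not pass by camera (4 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.39) but rose by fry (adjusted p = 2.09e-07).

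By edgeR's quasi-likelihood test 564 of 9512 genes rose with pDC output and 153 fell (Benjamini-Hochberg adjusted p under 0.05). That imbalance depended on scaling and on the libraries used: with library totals alone 205 rose and 230 fell, and with the number of detected genes in the fit 84 rose and 186 fell. In the 132 libraries of at least 20000 counts 247 rose and 148 fell, and with these thinned to 20000 counts each 337 rose and 297 fell, analyses chosen after the data were seen. Within single pools 872 rose and 98 fell in S1, 16 and 12 in D9JS27, 23 and 125 in JS91 and 64 and 49 in JS96. Without pool S1 62 rose and 104 fell, so the excess of genes that rose rested on S1. With no gene filter 1854 rose and 1835 fell, and with all 3 outputs in one fit 126 rose and 88 fell. In S1, D9JS27, JS91 and JS96, H2-Aa had values of -1.08, -1.07, -1.56 and -0.87.

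Clones that made more cDC1 cells carried fewer lymphoid transcripts. Ly6d, a surface protein gene of lymphoid progenitors (Entrez Gene 17068, chromosome 15, 74762056 to 74763567, GRCm38), fell by 1.16 on the log2 scale per doubling of cDC1 output (SE 0.119, adjusted p = 5.27e-14, n = 142 clones). Of 13 lymphoid genes 8 fell and 0 rose (8 fell adjusted over the list alone; camera adjusted p = 1.69e-17, and adjusted p = 1.01e-04 with an estimated correlation). They included the recombinase gene Rag1 (log2 change -0.84, SE 0.113), the B cell adaptor gene Blnk (-0.96, SE 0.132), the IL-7 receptor gene Il7r (-0.81, SE 0.115) and Dntt (-0.45, SE 0.0926), which encodes terminal deoxynucleotidyl transferase. Of 16 pDC genes 6 fell (12 adjusted over the list alone; camera adjusted p = 2.38e-15, and adjusted p = 0.00106 with an estimated correlation), among them Siglech (-0.72, SE 0.104), the chemokine receptor gene Ccr9 (-0.71, SE 0.107) and Spib (-0.61, SE 0.117).

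Genes of granule proteins rose with cDC1 output. Of 8 neutrophil and granule genes the myeloperoxidase gene Mpo (log2 change 0.38, SE 0.0927) and the cathepsin G gene Ctsg (0.37, SE 0.0801) rose and 0 fell (3 rose adjusted over the list alone; camera adjusted p = 9.43e-06, and adjusted p = 0.0223 with an estimated correlation). The basophil protease gene Mcpt8 (0.62, SE 0.0921), the fatty acid synthase gene Fasn (0.42, SE 0.0705) and the myosin gene Myo7a (0.66, SE 0.0818) rose as well. Of 4 mast cell, basophil and eosinophil genes 1 rose (1 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.434, but 9.18e-05 by fry, upward). Of 8 MHC class II genes only H2-Ob fell (-0.36, SE 0.086; 4 fell adjusted over the list alone; camera adjusted p = 5.12e-07, and adjusted p = 0.02 with an estimated correlation, but 0.0787 by fry). Of 7 genes that mark cDC1 cells 0 passed (1 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.441), and Id2, a transcriptional regulator gene on that list, had a value of -0.11, SE 0.0991. Batf3 was detected in too few libraries to be tested.

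In all, 462 genes rose with cDC1 output and 150 fell (edgeR, adjusted p under 0.05). With library totals alone 233 rose and 234 fell, with detected genes in the fit 68 rose and 167 fell, and with pDC and cDC2 output in the same fit 16 genes passed. Within single pools 182 rose and 76 fell in S1, 35 and 8 in D9JS27, 19 and 107 in JS91 and 64 and 35 in JS96. In the pools, in that order, Ly6d had values of -1.12, -1.51, -1.13 and -1.30.

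With higher cDC2 output, lymphoid and pDC genes fell and granule genes rose. Of 13 lymphoid genes 7 fell (10 adjusted over the list alone; camera adjusted p = 1.08e-17, and adjusted p = 1.01e-04 with an estimated correlation), including Ly6d (log2 change per doubling of cDC2 output -0.96, SE 0.125, n = 142 clones), Il7r (-0.72, SE 0.116) and Rag1 (-0.70, SE 0.121). Of 16 pDC genes 8 fell (12 adjusted over the list alone; camera adjusted p = 9.11e-15, and adjusted p = 0.00134 with an estimated correlation), including Siglech (-0.69, SE 0.106), Spib (-0.64, SE 0.123) and Irf7 (-0.50, SE 0.101). Of 8 granule genes Ctsg (0.43, SE 0.0788), Mpo (0.37, SE 0.0879) and the proteinase 3 gene Prtn3 (0.32, SE 0.0763) rose (3 rose adjusted over the list alone; camera adjusted p = 1.71e-05, and adjusted p = 0.0296 with an estimated correlation). Mcpt8 (0.64, SE 0.088), Fasn (0.37, SE 0.0686) and Ppargc1b (0.45, SE 0.08), which encodes a coactivator of mitochondrial genes, rose too.

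Of 8 MHC class II genes 3 fell with cDC2 output (6 adjusted over the list alone; camera adjusted p = 5.78e-08, and adjusted p = 0.0101 with an estimated correlation). H2-Aa was one (-0.50, SE 0.156), and its value with all 3 outputs in one fit was 0.10. Of 13 genes that mark cDC2 cells 0 passed (1 fell adjusted over the list alone; camera adjusted p = 0.22), with values of 0.10, SE 0.103 for Csf1r and -0.10, SE 0.0584 for the transcription factor gene Zeb2. In all, 428 genes rose and 159 fell (edgeR, adjusted p under 0.05). With library totals alone 229 rose and 274 fell, with detected genes in the fit 104 rose and 210 fell, and with all 3 outputs in one fit 14 passed. Within single pools 48 rose and 78 fell in S1, 35 and 18 in D9JS27, 11 and 104 in JS91 and 200 and 104 in JS96, and without pool JS96 64 rose and 98 fell.

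**Figure D3:**
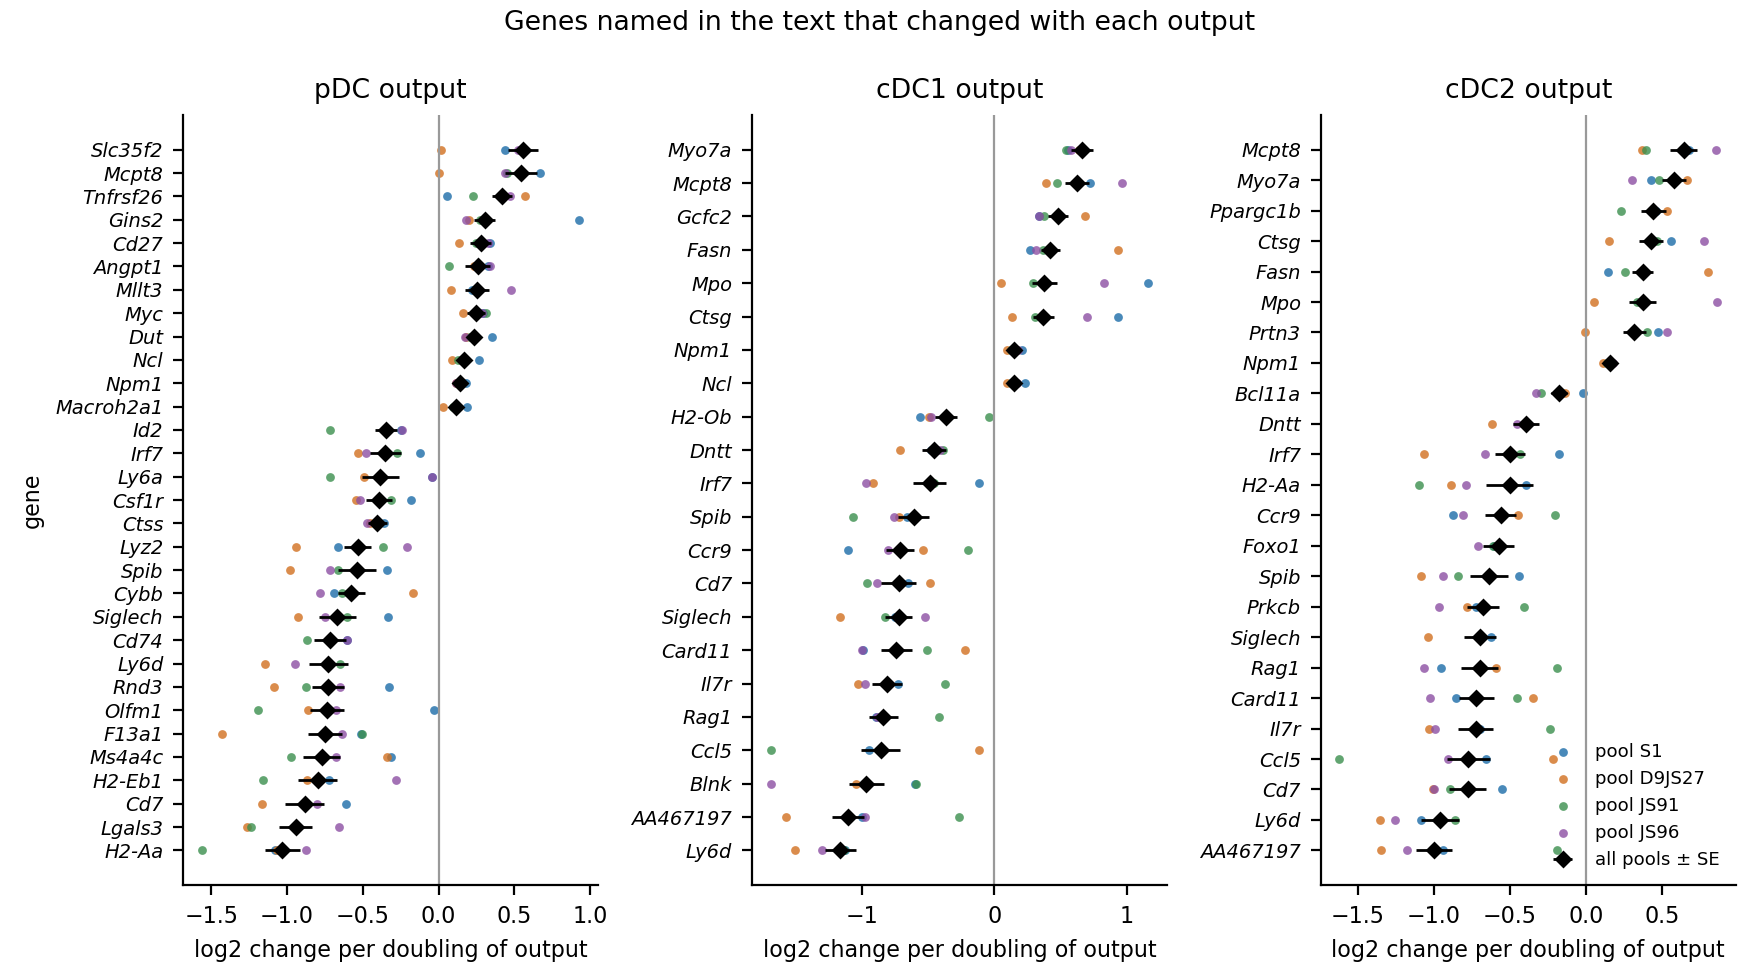
Log2 change per doubling of pDC, cDC1 and cDC2 output of genes named in the text that passed the test; black diamonds with bars are the fit over all pools ± SE (n = 142 clones), and coloured points are fits within each pool. H2-Aa lies at -1.03 with pDC output and Ly6d at -1.16 with cDC1 output.

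No-DC clones held more transcripts of several monocyte genes than clones that made pDCs, and of several lymphoid genes than clones that made cDCs. The monocyte antigen gene Ly6c2 (Entrez Gene 100041546, chromosome 15, 75108161 to 75112066, GRCm38) differed by -4.92, SE 1.34 on the log2 scale between pDC-only and no-DC clones (14 against 38 clones) and by -3.44, SE 0.744 between clones that made both and no-DC clones (60 against 38), but did not pass for cDC-only clones (-0.52, SE 0.762, adjusted p = 0.804). With each library left out in turn its pDC-only difference passed in 131 of 142 fits, with a weakest value of -4.19, adjusted p = 0.11 without 1 no-DC library of JS96. Lyz2 was lower in clones that made both (-4.16, SE 0.69), but did not pass in pDC-only clones (-4.30, SE 1.32, adjusted p = 0.0771) or cDC-only clones (0.00, SE 0.965, adjusted p = 1). Lyz2 had counts in 14 of 38 no-DC libraries, and 1 of these held 52.1% of their summed CPM. F13a1 had 0 counts over the 14 pDC-only libraries. Against a floor of 3 counts over the group, its pooled CPM in no-DC libraries was at least 1075-fold higher. Only 6 of 38 no-DC libraries held a count of F13a1, however, with a median of 0 CPM, and 1 held 64% of their summed CPM. Dntt was lower in cDC-only than in no-DC clones (-4.05, SE 0.702), while in pDC-only clones its value was 0.69, SE 0.748, adjusted p = 0.795. In clones that made both, Dntt (-0.96, SE 0.565, adjusted p = 0.275) and Rag1 (-1.61, SE 0.757, adjusted p = 0.163) did not pass by edgeR. Ly6d was lower in clones that made both (-4.26, SE 0.859), but did not pass in cDC-only clones (-1.75, SE 0.89, adjusted p = 0.313). H2-Aa was lower in clones that made both (-4.38, SE 0.801), with values of -4.80, SE 1.44, adjusted p = 0.0675 in pDC-only and 1.81, SE 0.78, adjusted p = 0.208 in cDC-only clones. The chemokine gene Ccl5 was lower in cDC-only clones (-7.32, SE 1.2) and in clones that made both (-6.59, SE 0.856), but not detectably in pDC-only clones (-1.66, SE 1.13, adjusted p = 0.62). It had counts in 9 of 38 no-DC libraries, and 1 of these held 58.3% of their summed CPM.

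Gene lists divided the classes in the same way. Of 13 monocyte and macrophage genes 3 were lower than in no-DC clones in pDC-only clones (5 adjusted over the list alone; camera adjusted p = 1.54e-13, and adjusted p = 0.0102 with an estimated correlation) and 8 in clones that made both (9 adjusted over the list alone; camera adjusted p = 6.75e-11, and adjusted p = 0.0193 with an estimated correlation), against 0 in cDC-only clones (0 adjusted over the list alone; camera adjusted p = 0.11). Of 13 lymphoid genes 5 were lower in cDC-only clones (10 adjusted over the list alone; camera adjusted p = 3.62e-26, and adjusted p = 7.65e-08 with an estimated correlation) and 4 in clones that made both (4 adjusted over the list alone; camera adjusted p = 4.48e-10, and adjusted p = 0.00357 with an estimated correlation). In pDC-only clones 0 were lower and 0 higher (0 and 0 adjusted over the list alone), with a shift upward (camera adjusted p = 0.0468, but adjusted p = 0.393 with an estimated correlation). Of 16 pDC genes 1 was lower in pDC-only clones (camera adjusted p = 0.3045). In cDC-only clones 1 was lower (camera adjusted p = 1.26e-09, and adjusted p = 0.0193 with an estimated correlation). In clones that made both 7 were lower (camera adjusted p = 1.7e-13, and adjusted p = 0.00357 with an estimated correlation). These comparisons of single classes were chosen after the average over classes was seen, and their lists were adjusted over 63 list tests. Their gene fits were repeated without each library in turn, but under no other alternative. Their list tests were repeated with an estimated correlation alone. In the average over the 3 DC-producing classes, 2 lymphoid genes were lower (5 adjusted over the list alone; camera adjusted p = 2.7e-08, and adjusted p = 0.00701 with an estimated correlation), 3 monocyte genes (9 adjusted over the list alone; camera adjusted p = 6.29e-08, but adjusted p = 0.0587 with an estimated correlation) and 3 of 16 pDC genes (5 adjusted over the list alone; camera adjusted p = 3.18e-09, and adjusted p = 0.0176 with an estimated correlation). By fry none of these 3 lists passed (adjusted p = 0.697, 0.814 and 0.785).

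Higher in the average over DC-producing classes than in no-DC clones were Cd24a, a surface protein gene on the cDC1 list (log2 difference 1.76, SE 0.437), Npm1 (0.90, SE 0.23), Ncl (0.90, SE 0.259) and the replication factor gene Rpa2 (1.47, SE 0.458), which passed in 103 of 142 fits without 1 library each. By class, each of these genes passed in clones that made both. None passed by edgeR in pDC-only (adjusted p of 0.145 to 0.415) or cDC-only clones (0.068 to 0.242). The Notch mediator gene Rbpj was higher in cDC-only clones (2.03, SE 0.568) and in clones that made both (2.09, SE 0.523), but not detectably in pDC-only clones (0.61, SE 0.724, adjusted p = 0.821). Ninl (5.08, SE 0.826), Ptger3 (4.09, SE 0.74) and Pced1b (3.92, SE 0.729) were detected in 2.63%, 7.89% and 7.89% of no-DC libraries, and the 3 counts of Ninl there give a pooled 0.175 CPM (95% Poisson interval 0.0361 to 0.512). They had counts in 5, 7 and 8 of 14 pDC-only and 6, 14 and 16 of 30 cDC-only libraries. In clones that made both these were 17, 32 and 30 of 60. Libraries of DC-producing clones detected more genes in general, as given above. In all, 289 genes were higher and 57 lower (edgeR, adjusted p under 0.05), beside a median of 0.35 over all tested genes. With library totals alone 234 were higher and 132 lower, and with detected genes in the fit 115 and 165. Within pool JS96 1343 genes were higher and 180 lower, against 14 and 140 in S1, 1 and 1 in D9JS27, and 0 in JS91 (edgeR, 511 at an unadjusted p under 0.05; median over all tested genes -1.20). Without pool JS96 35 were higher and 80 lower, so the excess of higher genes rested on that pool. Without the no-DC library that detected the most genes, left out after the data were seen, 536 passed. Fewer genes passed with output in either sister well as the class rule. Fewer also passed without the no-DC clones that had output in a sister well, which were left out after the data were seen. Both counts are given below.

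Clones classed as pDC-only and clones classed as cDC-only differed in lymphoid and myeloid genes. Some of them had output of the other branch, which reached 35.3 (cDC2) in a pDC-only clone and 13.6 (pDC) in a cDC-only clone. In a pDC-only clone of S1, cDC1 output was 1.65 in a sister well and cDC2 output 2.22 in the other. In the pDC-only clone of JS91 these values were 2.13 and 1.86. These clones thus had some cDC output in both sister wells, but of no single subset. Dntt (Entrez Gene 21673, chromosome 19, 41029275 to 41059525, GRCm38) averaged 3631 ± 3087 CPM (SD) in 14 pDC-only clones and 173 ± 424 CPM in 30 cDC-only clones (log2 difference 4.73, SE 0.783, adjusted p = 4.54e-05). Of 13 lymphoid genes 6 were higher in pDC-only clones and 0 lower (9 higher adjusted over the list alone; camera adjusted p = 1.99e-22, and adjusted p = 1.4e-06 with an estimated correlation), including Rag1 (6.79, SE 1.31), Rag2 (4.31, SE 1.15), the T cell kinase gene Lck (3.81, SE 0.924) and the chromatin organizer gene Satb1 (2.24, SE 0.518). All 287 Rag2 counts of the cDC-only libraries lay in 1 library of D9JS27, and Rag2 did not pass without 1 pDC-only library of JS96 (adjusted p = 0.196) or without 1 library of D9JS27 from a clone that made both (0.0504). Ccr9 (5.29, SE 1.15), the transcription factor gene Tox (5.55, SE 1.08) and the nucleotide sugar receptor gene P2ry14 (5.24, SE 0.932) were higher as well. Of 16 pDC genes only Ccr9 passed (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 5.78e-04, but adjusted p = 0.193 with an estimated correlation).

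Several myeloid genes, of monocytes and of granules, were lower in pDC-only than in cDC-only clones. Csf1r averaged 2.2 ± 8.23 CPM (SD) in pDC-only and 208 ± 268 CPM in cDC-only clones (log2 difference -6.15, SE 1.37, adjusted p = 0.00442). The G-CSF receptor gene Csf3r (-5.78, SE 1.52), the myeloid transcription factor gene Cebpa (-5.09, SE 1.17), Mpo (-4.71, SE 1.25), the chemokine gene Ccl9 (-4.94, SE 1.21) and H2-Aa (-6.61, SE 1.57) were lower too. Csf3r did not pass without 1 cDC-only library of S1 (-4.31, adjusted p = 0.172) or 1 of JS96 (-5.04, adjusted p = 0.0822), nor Mpo without 1 cDC-only library of JS96 (-4.30, adjusted p = 0.0579) or 1 pDC-only library of D9JS27 (-4.50, adjusted p = 0.0505). Of the pDC-only libraries 1 held all 22 Csf1r counts, and without 1 of JS96 the values of H2-Aa (-10.00, adjusted p = 3.80e-04) and Mpo (-8.84, adjusted p = 0.00122) were lower still. F13a1 had 0 counts over the pDC-only libraries and 1355 over the cDC-only libraries, where pooled CPM was at least 142-fold higher against a floor of 3 counts over the group. Lgals3 had 1 count in pDC-only libraries, a pooled 0.108 CPM (95% Poisson interval 0.00274 to 0.603), against 157 CPM in cDC-only libraries. Of 13 monocyte and macrophage genes 3 were lower (9 adjusted over the list alone; camera adjusted p = 6.01e-16, and adjusted p = 0.00304 with an estimated correlation), and of 8 granule genes 3 (5 lower and 1 higher adjusted over the list alone; camera adjusted p = 3.83e-05, and adjusted p = 0.0473 with an estimated correlation). Of 19 cytokine receptor genes 2 were lower and 1 higher (4 and 3 adjusted over the list alone; camera adjusted p = 0.0831). Of 8 MHC class II genes only H2-Aa was lower (5 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00534, but adjusted p = 0.23 with an estimated correlation).

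**Figure D4:**
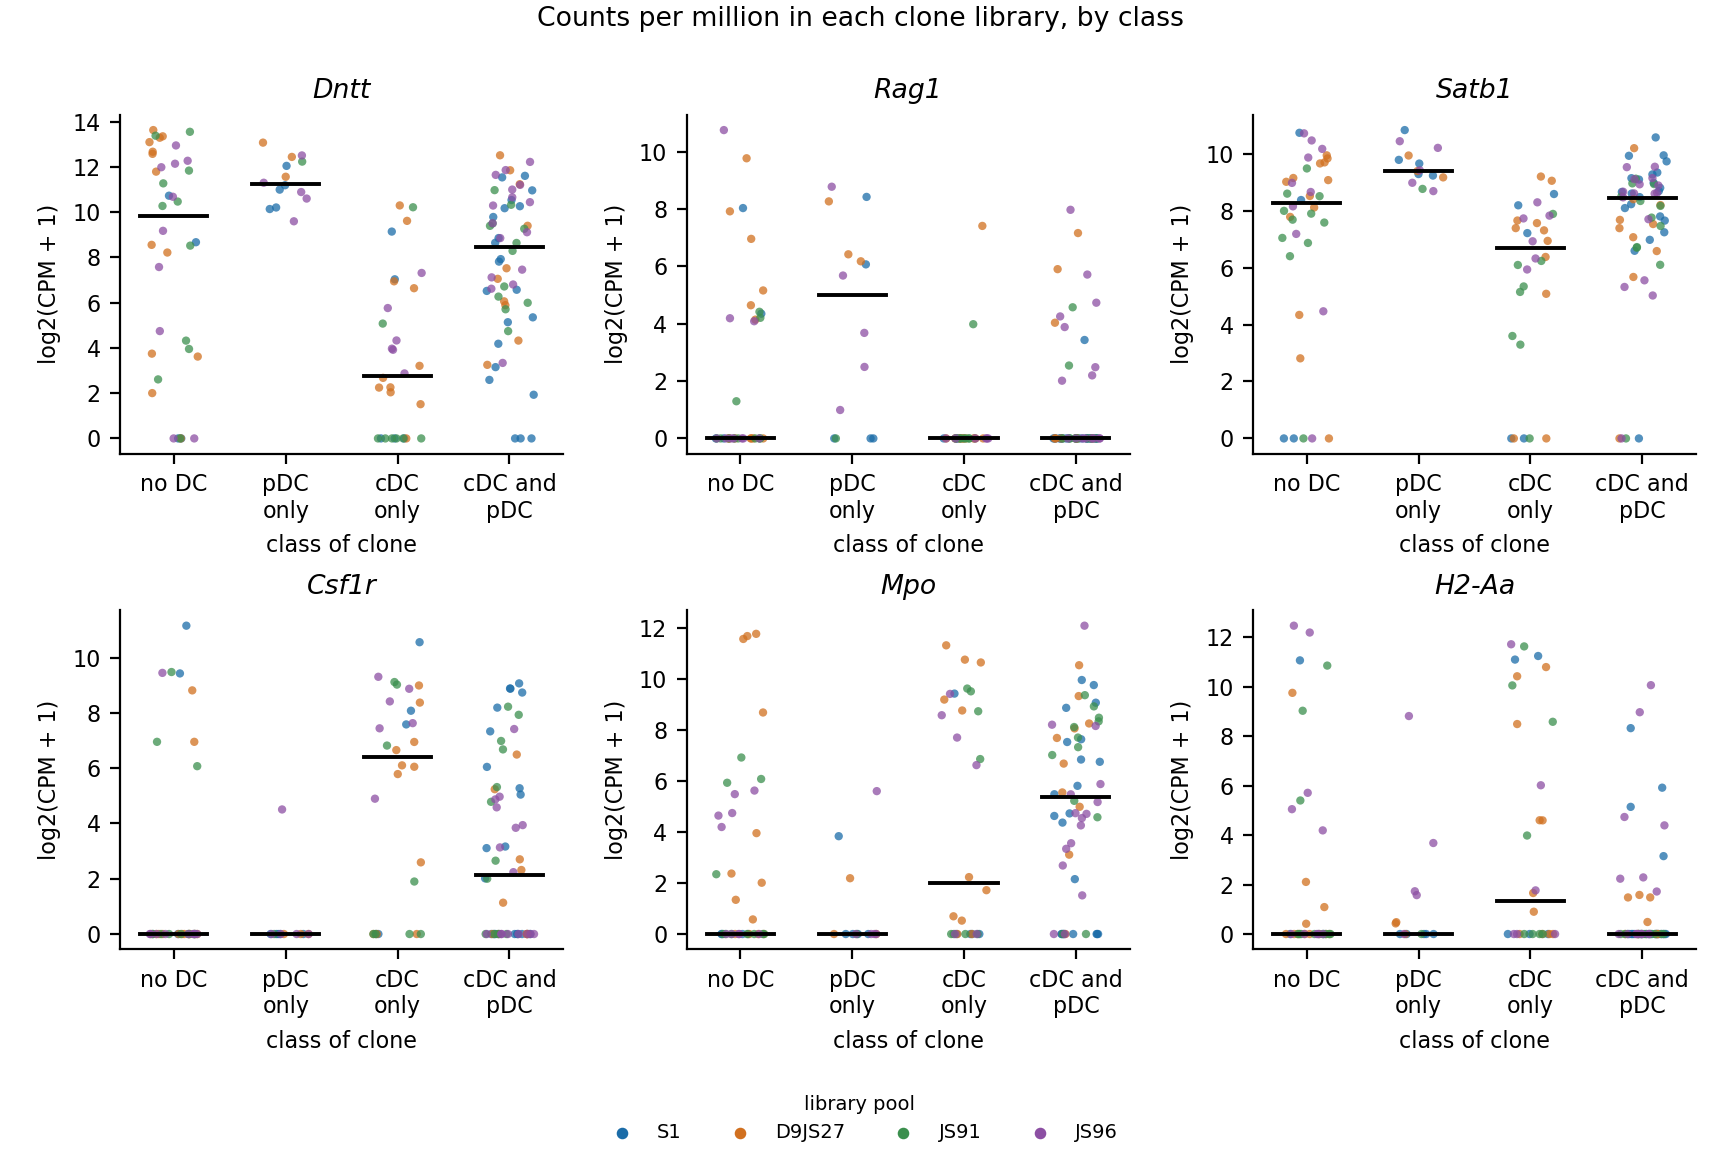
Log2(CPM + 1) of Dntt, Rag1, Satb1, Csf1r, Mpo and H2-Aa in each of 142 clone libraries, by class of clone; points are libraries coloured by pool, and black bars are medians. Dntt has a median of 2436 CPM in pDC-only and 5.9 CPM in cDC-only clones.

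In all, 69 genes were higher in pDC-only clones and 42 lower (edgeR, adjusted p under 0.05). Pool JS91 holds 1 pDC-only clone, and within single pools 0 (S1), 0 (D9JS27), 3 (JS91) and 5 (JS96) genes passed by edgeR, with 1617, 466, 316 and 595 at an unadjusted p under 0.05. Dntt differed by 4.04, 4.45, 5.31 and 5.78 in those pools. By DESeq2's Wald test 13 genes were higher and 23 lower.

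Few genes separated cDC1 from cDC2 output. With the 3 outputs in one fit, the zinc finger gene Zgpat (Entrez Gene 229007; slope difference, cDC1 minus cDC2, 1.89, SE 0.372, adjusted p = 0.00976) and the tubulin gene Tubb2a (1.30, SE 0.285, adjusted p = 0.0469) passed, and 0 genes had a steeper cDC2 slope by edgeR. In fits without 1 library each, Zgpat passed in 140 of 142 and Tubb2a in 93 of 142. Without a no-DC library of JS96 Zgpat had 0.99, adjusted p = 0.606. Without a library of S1 from a clone that made both Tubb2a had 0.67, adjusted p = 0.894. Among the next lowest p values, Pak4 (1.28, SE 0.297) leaned to cDC1, and Umad1 (-1.46, SE 0.346) and Nkiras1 (-1.60, SE 0.379) to cDC2, and these did not pass. At an unadjusted p under 0.05 there were 538 genes, against 476 expected by chance, and DESeq2 and limma-voom called 0 and 0. Other settings called more genes, among them no gene filter, thinned libraries, pool S1 alone and edgeR's newer fit, as counted below. In simulated data of this design 5% of genes with a slope difference of 0.5 and 57% of those with 1 were found. Neither the cDC1 list (camera adjusted p = 0.734) nor the cDC2 list (camera adjusted p = 0.976) differed between the slopes.

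Several regulators of DC development did not pass in any comparison. The transcription factor gene Irf8 had log2 changes of -0.04, SE 0.0598, 0.00, SE 0.0592 and 0.01, SE 0.0594 per doubling of pDC, cDC1 and cDC2 output. Those of Flt3, the receptor gene for the cytokine in the culture, were 0.10, SE 0.0571, -0.09, SE 0.0548 and -0.08, SE 0.0548, and those of the corepressor gene Bcor were -0.05, SE 0.062, 0.16, SE 0.0713 and 0.18, SE 0.072. Kit, Cd34, Tcf4 and Zeb2 did not pass either, while Id2 fell with pDC output (-0.35, SE 0.0749). Against no-DC clones Id2 was higher in cDC-only clones (2.17, SE 0.654) and lower in clones that made both (-1.80, SE 0.591), but these passed in 118 and 139 of 142 fits without 1 library each. The weakest values were 1.61, adjusted p = 0.167 without 1 cDC-only library of JS91 and -0.97, adjusted p = 0.358 without 1 no-DC library of JS96.

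The remaining lists gave smaller or unstable shifts with pDC output. Of 24 DC transcription factor genes 4 fell (4 adjusted over the list alone; camera adjusted p = 3.45e-05, but adjusted p = 0.0656 with an estimated correlation). Of 13 lymphoid genes 2 fell (2 adjusted over the list alone; camera adjusted p = 0.0211, but adjusted p = 0.398 with an estimated correlation), with a median of 0.04 but a mean of -0.12. Of 30 mitosis genes 0 passed (0 adjusted over the list alone; camera adjusted p = 0.0371, but adjusted p = 0.651 with an estimated correlation). Of 8 BCOR-PRC1.1 complex genes 0 passed (0 adjusted over the list alone; camera adjusted p = 0.994, but 6.80e-04 by fry, upward). The neutrophil and granule list did not pass by camera (adjusted p = 0.39) but rose by fry (1.71e-04). For the mast cell, basophil and eosinophil list camera leaned downward (adjusted p = 0.913), but fry passed upward (0.00248). The cDC1 list leaned downward without passing (camera adjusted p = 0.0742). Of 3 erythroid and megakaryocyte genes 1 fell (1 adjusted over the list alone; camera adjusted p = 0.352), with a median of 0.02 and a mean of -0.10. Of 12 immediate early and stress genes 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.128), and of 15 mitochondrially encoded genes 3 rose (6 adjusted over the list alone; camera adjusted p = 0.536, but 0.00335 by fry, upward).

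**Figure D5:**
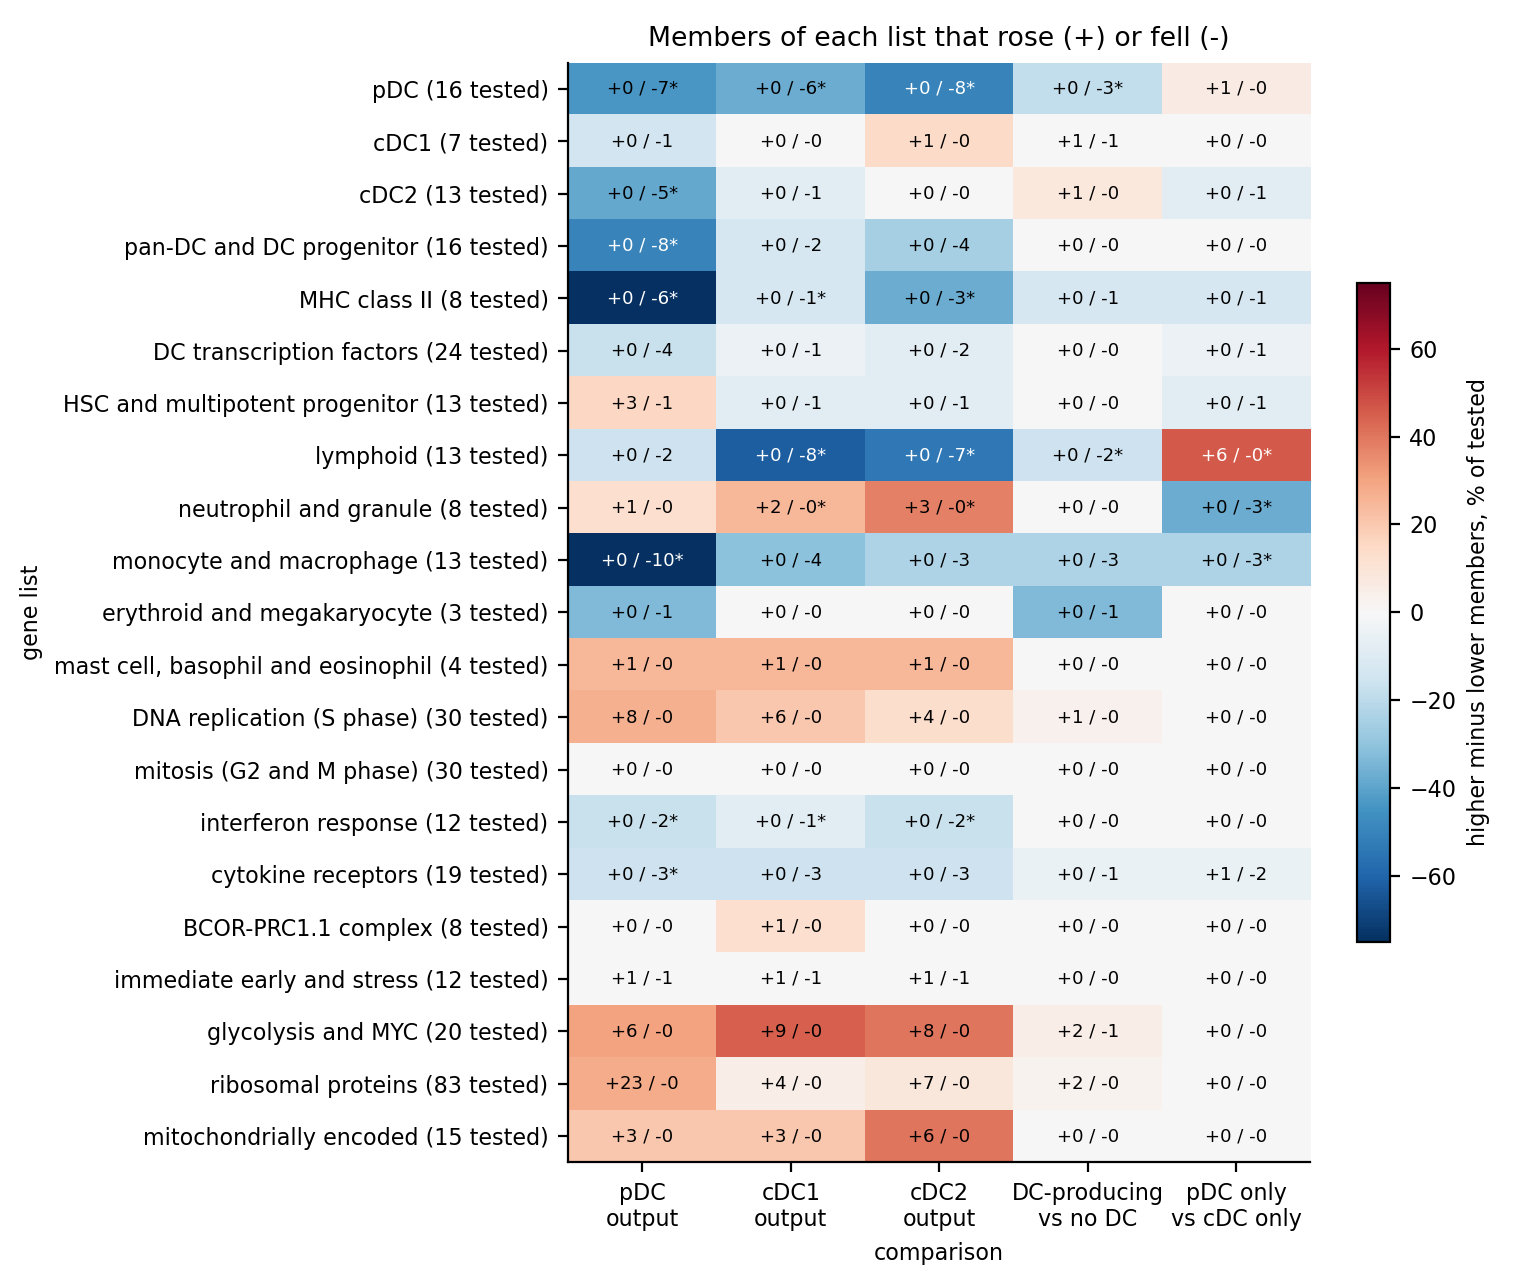
Number of members of each of 21 gene lists that rose or were higher (+) and fell or were lower (-) at adjusted p under 0.05 in 5 comparisons, coloured by their difference as a percent of the tested members; stars mark lists whose set test passed with an estimated correlation. Monocyte genes fell with pDC output (10 of 13), and lymphoid genes fell with cDC1 output (8 of 13).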

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

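Chosen only after the result was seen were the tests by thinning, by library totals, by counts per well and by detected genes at similar totals.

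Genes that rose made up 78.7% of the genes that passed with pDC output. With library totals alone the share was 47.1%, so the scaling factors may account for the imbalance. Without pool S1 it was 37.3%, in S1 alone 89.9% and in JS91 alone 15.5%, so the imbalance rested on S1. In the 132 libraries of at least 20000 counts it was 62.5%, and with these thinned to 20000 counts each 53.1%, where more genes rose (337 against 247) and more fell (297 against 148), so thinning does not show that depth made the excess, and depth stays open. No biological explanation of the imbalance was tested.

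MHC class II and monocyte genes fell with pDC output, 16 of the members on these lists. After thinning 16 still fell, which argues against depth as the cause. Free RNA was weighed in pools JS91 and JS96, where 8 wells with 0 sorted cells held 3.6 times the share of these genes in 21 no-DC libraries (95% bootstrap interval 0.0281 to 6.84), and that upper bound met the prediction for free RNA written in advance, although only 3 of these wells held any such count. By counts per well the ratio was 0.0469 (6.71e-05 to 0.457; mean 35.8 against 763 counts), which argues against free RNA as the main source there, if wells share it evenly. S1 and D9JS27 held too few such wells, and a difference in state between clones stays open.

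The D9JS27 well with 0 sorted cells stood apart from the other 9 such wells in total count (1037727, next 21111) and in detected genes (6093, next 1976). The outlier test used has a chance rate of about 1 in 20 for values of a single normal population. These wells came from several pools, and this was the only one of the pool with the highest median total, so that rate may not hold. A mixture of the reads of that pool at the total of this well would detect 12356 genes, and the well held 49.3% of that, which argues against a mixture. Its highest correlation across genes with a clone library of its pool was 0.748, inside the range of the clone libraries' own highest values (0.472 to 0.881). The prediction for carry-over from 1 library, a value above that range, was not met. A noisy copy of 1 library could also fall short of it, so this test leaves carry-over open. Its detected genes lay within the 4080 to 7881 of 14 clone libraries of similar total, so cells in a well recorded as empty are a candidate explanation. No biological explanation was tested.

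The unclassed library of pool JS91 held 61944 counts, above the highest of its pool's 6 wells with 0 sorted cells (18262). It detected 3765 genes, above their highest of 1623. Of the 10 clones whose RNA well received 0 sorted cells, 4 had DC output in their sister wells, up to 79.5.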

How the results depend on the processing

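Chosen only after the result was seen were the alternatives marked as added. Counts of genes that moved by more than 1.5 times are given by setting, for the slopes with pDC, cDC1 and cDC2 output (717, 612 and 587 as reported), DC-producing clones (346), pDC-only against cDC-only clones (111) and the cDC1 minus cDC2 slope difference (2), and the cause was not tested. With no gene filter, 3689 (pDC slope), 3527 (cDC1 slope), 3671 (cDC2 slope), 1814 (DC-producing), 1378 (pDC-only) and 1311 (slope difference) passed. With DESeq2's Wald test, 36 (pDC-only) and 0 (slope difference) passed. With DESeq2's size factors, 4 (slope difference) passed. With library totals alone, 435 (pDC slope) and 5 (slope difference) passed. With genes with a count in at least 50% of libraries, 306 (pDC slope), 170 (cDC1 slope), 143 (cDC2 slope), 71 (DC-producing), 12 (pDC-only) and 0 (slope difference) passed. With no library filter, 6 (slope difference) passed. With libraries of at least 2000 detected genes, 396 (pDC slope), 351 (cDC1 slope), 220 (DC-producing) and 1 (slope difference) passed. With libraries of 3 or more sorted cells, 392 (pDC slope), 217 (cDC1 slope), 154 (cDC2 slope), 43 (DC-producing) and 14 (slope difference) passed. With limma-voom, 2057 (pDC slope), 2251 (cDC1 slope), 2216 (cDC2 slope), 1304 (DC-producing) and 0 (slope difference) passed. With sorted cells left out of the fit, 12 (slope difference) passed. With pool left out of the fit, 295 (pDC slope), 374 (cDC1 slope) and 13 (slope difference) passed. With detected genes in the fit, 270 (pDC slope), 235 (cDC1 slope), 314 (cDC2 slope) and 8 (slope difference) passed. With filler shares in the fit, 654 (DC-producing) passed. Leaving out pool S1, 166 (pDC slope), 161 (cDC1 slope), 380 (cDC2 slope), 195 (DC-producing), 38 (pDC-only) and 7 (slope difference) passed. Leaving out pool D9JS27, 198 (DC-producing), 188 (pDC-only) and 37 (slope difference) passed. Leaving out pool JS91, 300 (pDC slope), 295 (cDC1 slope), 316 (cDC2 slope), 814 (DC-producing), 62 (pDC-only) and 11 (slope difference) passed. Leaving out pool JS96, 302 (pDC slope), 211 (cDC1 slope), 162 (cDC2 slope), 115 (DC-producing) and 19 (slope difference) passed. In pool S1 alone, 258 (cDC1 slope), 126 (cDC2 slope), 154 (DC-producing), 0 (pDC-only) and 92 (slope difference) passed. In pool D9JS27 alone, 28 (pDC slope), 43 (cDC1 slope), 53 (cDC2 slope), 2 (DC-producing) and 0 (pDC-only) passed. In pool JS91 alone, 148 (pDC slope), 126 (cDC1 slope), 115 (cDC2 slope), 0 (DC-producing), 3 (pDC-only) and 42 (slope difference) passed. In pool JS96 alone, 113 (pDC slope), 99 (cDC1 slope), 304 (cDC2 slope), 1523 (DC-producing), 5 (pDC-only) and 15 (slope difference) passed. With output of sister well 1 only, 272 (cDC1 slope), 274 (cDC2 slope) and 4 (slope difference) passed. With output of sister well 2 only, 4 (slope difference) passed. With output as present or absent, 307 (pDC slope), 316 (cDC1 slope) and 155 (cDC2 slope) passed. With edgeR's newer quasi-likelihood fit (added), 1246 (pDC slope), 1589 (cDC1 slope), 1613 (cDC2 slope), 875 (DC-producing), 319 (pDC-only) and 32 (slope difference) passed. With libraries of at least 20000 counts thinned to that number (added), 571 (DC-producing), 197 (pDC-only) and 84 (slope difference) passed. With the same libraries not thinned (added), 395 (pDC slope), 363 (cDC1 slope), 230 (DC-producing) and 1 (slope difference) passed. With the no-DC library of most detected genes left out (added), 536 (DC-producing) and 9 (slope difference) passed. With no-DC clones with any DC output left out (added), 187 (DC-producing) and 0 (slope difference) passed. With all 3 outputs in one fit, 214 (pDC slope), 16 (cDC1 slope) and 14 (cDC2 slope) passed. With output in either sister well as the class rule, 83 (DC-producing) passed. With each library left out in turn (added; the pDC, cDC1 and cDC2 slopes were not rerun so), 301 to 536 (DC-producing), 97 to 123 (pDC-only) and 0 to 11 (slope difference) passed. No paired analysis was possible because replicate numbers follow only the order of deposit.

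Of 126 list tests 62 passed by camera and 22 with an estimated correlation. fry, which tests a list against no change instead of against other genes, gave the opposite direction in 39, of which 17 passed in neither test and are not listed. The other 22 are given with adjusted p by fry. On the pDC slope these were the lists of DC transcription factors (0.469), lymphoid (0.285), mast cell, basophil and eosinophil (0.00248) and immediate early and stress (0.0274). On the cDC1 slope they were DC transcription factors (0.304), HSC and multipotent progenitor (0.0428), monocyte and macrophage (0.895) and cytokine receptors (0.389). On the cDC2 slope they were DC transcription factors (0.285), monocyte and macrophage (0.635) and cytokine receptors (0.38). For DC-producing clones they were cDC1 (0.0096), cDC2 (0.0331), pan-DC and DC progenitor (0.475), MHC class II (0.925), DC transcription factors (0.0017), HSC and multipotent progenitor (0.0069), erythroid and megakaryocyte (0.943), interferon response (0.663), cytokine receptors (0.049), immediate early and stress (0.0227) and mitochondrially encoded (0.0329). Of lists with the same direction 18 passed by camera alone and 13 by fry alone. By camera alone passed, with adjusted p by fry, pDC (0.179), cDC2 (0.789), interferon response (0.387) and cytokine receptors (0.984) for the pDC slope. Others were pan-DC and DC progenitor (0.693), MHC class II (0.0787) and interferon response (0.616) for the cDC1 slope. On the cDC2 slope these were pan-DC and DC progenitor (0.711) and interferon response (0.469). For DC-producing clones they were pDC (0.785), lymphoid (0.697) and monocyte and macrophage (0.814). For pDC-only against cDC-only clones these were cDC2 (0.178), pan-DC and DC progenitor (0.14) and MHC class II (0.287). For the slope difference they were mitosis (G2 and M phase) (0.57), ribosomal proteins (0.48) and mitochondrially encoded (0.256). By fry alone passed HSC and multipotent progenitor (2.09e-07), neutrophil and granule (1.71e-04), BCOR-PRC1.1 complex (6.80e-04) and mitochondrially encoded (0.00335) for the pDC slope. Further lists were mast cell, basophil and eosinophil (9.18e-05), BCOR-PRC1.1 complex (1.71e-04), ribosomal proteins (0.00267) and mitochondrially encoded (0.00337) for the cDC1 slope, with mast cell, basophil and eosinophil (7.62e-06) and BCOR-PRC1.1 complex (0.001) for the cDC2 slope. The last were neutrophil and granule (0.00335), mast cell, basophil and eosinophil (5.78e-05) and BCOR-PRC1.1 complex (8.47e-05) for DC-producing clones. Clone libraries exceeded the well with 0 sorted cells by 0.472 log10 counts in S1, differed by -0.0106 in D9JS27 and exceeded it there by 375 detected genes. Sorted cells and log10 total count correlated with r = -0.108 within JS96.

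Genes named in the text gave 5468 values under alternatives, of which 4665 kept direction and side of the threshold, 697 no longer passed, 92 newly passed and 14 turned. Turned log2 values were, with all 3 outputs in one fit, Ly6a (pDC slope, 0.05), Irf7 (cDC1 slope, 0.001) and H2-Aa (cDC2 slope, 0.10). Others were, in pool D9JS27 alone, Prtn3 (cDC2 slope, -0.004) and Ccl5 (pDC-only, -4.32). Others were, with output as present or absent, H2-Aa (cDC2 slope, 0.09). Others were, in pool JS96 alone, F13a1 (DC-producing, 2.37). Others were, in pool S1 alone, Ccr9 (DC-producing, 0.17), Uaca (pDC-only, -0.26) and Ccl9 (pDC-only, 0.85). Others were, in pool JS91 alone, Ncl (DC-producing, -0.48), AA467197 (pDC-only, -0.49), Rag1 (pDC-only, -2.35) and Sla2 (pDC-only, -4.24). The values of F13a1, AA467197 and Uaca (SE of 1931 or more) carry no information, since in those pools AA467197 and Uaca had 0 counts in both groups and F13a1 had 0 in no-DC and pDC-only clones. Over all 308 genes and comparisons that the rule named, 44 of 9080 values turned, and 0 of those passed.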

Other observations

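Chosen only after the result was seen were the counts over other splits, the relation of detected genes to DC output and the comparison with random lists.

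Replication and growth genes also rose with cDC output. Of 30 DNA replication genes 6 rose with cDC1 output (15 adjusted over the list alone; camera adjusted p = 1.68e-12, but adjusted p = 0.075 with an estimated correlation) and 4 with cDC2 output (15 adjusted over the list alone; camera adjusted p = 1.07e-10, but adjusted p = 0.106 with an estimated correlation). Of 20 glycolysis and MYC genes 9 rose with cDC1 output (15 adjusted over the list alone; camera adjusted p = 3.58e-07, but adjusted p = 0.0933 with an estimated correlation), among them Npm1 (log2 change 0.15, SE 0.0327) and Ncl (0.15, SE 0.0358). Of 15 mitochondrially encoded genes 6 rose with cDC2 output (9 adjusted over the list alone; camera adjusted p = 0.00916, but adjusted p = 0.495 with an estimated correlation). The transcription factor gene Foxo1 (-0.57, SE 0.1) and the signalling adaptor gene Card11 (-0.72, SE 0.114) fell with cDC2 output.

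Among no-DC clones a hypothesis was that each carried either lymphoid or monocyte genes. Scores of these lists, adjusted for pool, detected genes and sorted cells, correlated with Pearson's r = -0.688 (rho = -0.682, n = 38, permutation p = 1e-05 for r, the smallest possible, and 4e-05 for rho; adjusted p = 4.4e-05 and 1.10e-04 over 22 p-values). Without the 2 clones farthest from the median r was -0.696. Within pools it was -0.672 in D9JS27, -0.516 in JS91 and -0.763 in JS96, and S1 held too few clones. Random lists of matched expression gave a median r of 0.0691 and a lowest of -0.432 in 1000 pairs. Their genes were drawn independently, so these lists lack the shared variation of a lineage list. That comparison therefore cannot show how unusual the observed r is for a pair of lineage lists. In 104 DC-producing clones r was -0.371 (adjusted p = 3.52e-04), but it passed within none of their classes, so that value may mix classes: 0.283 in 14 pDC-only clones (adjusted p = 0.391), -0.331 in 30 cDC-only clones (adjusted p = 0.15) and -0.17 in 60 that made both (adjusted p = 0.249). The difference between DC-producing and no-DC clones was not tested. The values are consistent with opposed lymphoid and monocyte programs among no-DC clones.

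Another hypothesis was that genes separating pDC-only from cDC-only clones follow the balance of outputs in clones that made both, which were outside that contrast but shared its fit. Across these 60 clones the score (higher minus lower genes) correlated with log2 of pDC over cDC output with r = 0.516 (rho = 0.515, permutation p = 1e-05 each, adjusted p = 4.4e-05; r without 2 clones 0.555). Within pools r was 0.435 in S1, 0.84 in D9JS27, 0.793 in JS91 and 0.584 in JS96. The fixed lymphoid list gave r = 0.436 (adjusted p = 8.29e-04), the monocyte list -0.472 (adjusted p = 4.4e-05) and the pDC list 0.0327 (adjusted p = 0.827). Lymphoid against myeloid genes at day 2.5 may thus go with the later balance of pDCs and cDCs.

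Detected genes were related to DC output with r = 0.395 over 147 clones (rho = 0.401, permutation p = 1e-05 each; r without 2 clones 0.452; within pools 0.478 in S1, 0.535 in D9JS27, 0.22 in JS91 and 0.712 in JS96).

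Other splits, made by permuting outputs or classes among the libraries of a pool, gave fewer genes in most comparisons. The real split alone gave as many genes for the pDC slope (1 of 50 splits, 717 genes, highest other 30) and the cDC1 slope (1 of 50, 612 against 39). So it did for the cDC2 slope (1 of 50, 587 against 43) and DC-producing clones (1 of 50, 346 against 122). Chance is thus an unlikely source of these 4 counts, if clones of a pool can be exchanged. The labels do not give the mice they came from. For pDC-only against cDC-only clones 2 of 50 splits gave as many genes, a share just under 5%, with 111 genes in the real one and 154 in the highest other. For the slope difference chance could not be excluded (32 of 35 splits, 2 genes against 15).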
